A study of Mus musculus with 2 samples.

How the data were processed

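Single-cell RNA was measured in 2 libraries of CD45-sorted cells from subcutaneous MFC tumours, 1 from PBS-treated control mice and 1 from mice treated with thonzonium bromide. Per the labels, tumours were digested with collagenase and DNase, red blood cells were lysed, and libraries were made with a 10x Genomics 3' kit. The labels do not state how many mice entered a library, and both samples carry the same treatment protocol, so groups were taken from the treatment label of each sample. The deposited files hold integer UMI counts per gene and barcode for 32285 genes. Per the file headers, the counts were written by Cell Ranger 6.1.2, and the submitters' processing notes also name Seurat 3.0, R 3.5.3 and the mm10 genome. No deposited file gives cell types or a list of filtered cells. The lowest barcode total was 500 UMIs in the control and 501 in the treated library, so a lower bound on UMIs had been set before deposit.

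Cells with at least 200 detected genes and at most 20% mitochondrial UMIs were kept. This removed 420 control and 263 treated barcodes for few genes and 1138 and 719 for mitochondrial UMIs, with some barcodes in both counts, leaving 6419 and 5833 cells with 44148296 and 50871432 UMIs. Scrublet, run on each library in scanpy 1.11.5, marked 0 control cells and 1 treated cell as doublets, so it was judged not to have worked and no cells were removed as doublets. Counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes were reduced to 30 principal components after leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor variable segment, Xist and Y-linked genes. A graph of 15 neighbours was clustered with Leiden (leidenalg 0.10.2) at resolution 1 over both libraries without batch integration. The lymphoid cells and the myeloid cells were then clustered again within themselves in the same way.

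Cluster names were taken only from 23 marker lists fixed before the data were examined. A list had to lead by its mean log2 level over the median cluster and have at least 3 markers at 50 CPM or more and 2-fold above that median. Clusters led by markers of another type, or of low depth with no marker of their own among the 10 leading genes, stayed unnamed. A rule for ties, a rule that erythroid markers must lead an erythroid-like cluster, a block on clusters led by muscle genes and a block on subtypes led by markers of a sister subtype were set after the clusters had been seen. Together the unnamed clusters held 1219 control and 701 treated cells. They comprised a low-depth cluster led by Hes1 and Ace (559 and 352 cells), a cluster led by the osteoclast genes Ctsk, Mmp9 and Acp5 (485 and 311), a cluster led by the muscle genes Acta1 and Tnnc2 (110 and 38) and a cluster led by neutrophil and haemoglobin genes (65 and 0, of which a count of 0 allows up to 0.0632% of treated cells). The 10 leading genes of the Ctsk-led cluster also held the granzyme genes Gzmf, Gzmg, Gzmd and Gzme. Its depth was low, and its monocyte and CD8 T cell lists scored 2.07 and 2.06.

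UMIs were summed per gene, class and library and expressed as CPM, the usual scaling of counts by the class total, with exact Poisson 95% intervals. The ratio of treated to control CPM has an exact conditional binomial interval, and shares of cells have exact Clopper-Pearson intervals. UMIs count molecules, but cells of 1 library share a tumour, a sort and a droplet run, so all intervals and limits cover counting error only. A class needed at least 200 cells in each library for gene levels. The T-like, NK-like, monocyte/macrophage-like, B-like and dendritic-like classes met this.

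Each of 25 gene lists fixed before the data were examined was summarised by the median log2 ratio of its members with at least 50 UMIs. That median was placed among 10000 random lists of the same size drawn within 20 bins of mean expression. The percentile describes these libraries and is no test. Lists with under 3 measured members have no value. For shares of cells with a UMI, each cell was thinned to 1000 UMIs, shallower cells were left out, and the share in a class that should lack the gene was taken as background.

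Named genes followed a rule fixed in advance. In the 4 largest classes these were the 12 genes with the highest and the 12 with the lowest ratio among genes with at least 200 UMIs, at least 50 CPM in a library, a counting interval that excludes 1, and at least 25% of the highest CPM of any class. Mitochondrial, ribosomal, haemoglobin, antigen receptor, sex-linked and unnamed model genes were left out. The most abundant member of each list and up to 2 members with the highest and 2 with the lowest ratio were added. The examples printed were picked from these for known function, and 2 list members picked by the rule are not reported here, though they stay in the list median. T cell receptor segments and the genes set beside them within the CD8 T-like subclusters were chosen after their values were seen. Gene positions come from GENCODE M21 on GRCm38, the assembly known as mm10.

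Counting intervals and list percentiles were checked on simulated Poisson counts drawn from class means pooled over both libraries, at the real depths. The draws had no spread between cells or libraries beyond counting error and no correlation between genes. They check the calculation, not how the intervals or percentiles hold for real replicates or co-regulated lists. For T-like cells, over 10378 genes, 96.0% of genes set 2-fold higher and 100% of genes set 4-fold higher had an interval on the correct side of 1, and 95.4% of intervals for unchanged genes covered the true ratio. For monocyte/macrophage-like cells, over 9698 genes, the values were 100%, 100% and 95.3%. Of 200 unchanged random lists, 6.0% in T-like and 2.5% in monocyte/macrophage-like cells fell outside the central 95%.

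Alternatives were tried for the cell filters, clustering resolution, joint or separate clustering, per-cell classes, doublet scores, scaling, UMI minimums, cluster weights and thinning depth. Statistics were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. No p-value, standard error or count of changed genes was computed, since cells are not replicates. The tests of a library shift for the Gzmk-led subcluster and of unnamed barcodes replaced earlier versions whose results had been seen. Gene list medians planned for neutrophil-like cells were not run because that class was too small.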

Results

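Immune cells were isolated by sorting for the pan-leukocyte marker CD45 from subcutaneous tumours of BALB/c mice inoculated with MFC cells, a mouse forestomach carcinoma line, and were profiled by droplet-based single-cell RNA sequencing. A single library came from mice given PBS (control) and a single library from mice given thonzonium bromide, a cationic surfactant known as an inhibitor of vacuolar ATPase proton transport, at 50 mg/kg from day 6, with tumours taken on day 10. The deposited counts held 7803 barcodes with 46348444 unique molecular identifiers (UMIs) in the control and 6724 barcodes with 52973138 UMIs in the treated library. After filtering, 6419 control and 5833 treated cells remained, with medians of 4300 and 7259 UMIs and of 1546 and 2332 genes per cell. Haemoglobin genes took 8.64% of control and 1.16% of treated UMIs, most of them in erythroid-like barcodes, and a UMI of the beta-globin gene Hbb-bs was found in 88.4% of control and 44.0% of treated cells. With 1 library per group no difference below has a replicate check or a test, and the 95% intervals cover counting error only. Values therefore describe these 2 libraries, not the treatment.

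The first comparison asked which immune cells made up the tumour infiltrate in each library. Monocyte/macrophage-like cells, the mononuclear phagocytes of the infiltrate, made up 8.62% of control cells (553 cells, interval 7.94 to 9.33) and 26.2% of treated cells (1527 cells, 25.1 to 27.3), a ratio of 3.04 (2.76 to 3.36). B-like cells, the antibody lineage, made up 3.63% (3.19 to 4.12) and 8.78% (8.06 to 9.53), a ratio of 2.42. T-like cells were at 22.7% and 21.2%, and natural killer (NK)-like cells, innate cytotoxic lymphocytes, at 21.6% and 19.5%. Dendritic-like cells, which present antigen to T cells, were at 5.42% and 5.57%, with overlapping intervals, but at 8.26% and 6.51% of the named immune cells. Plasmacytoid dendritic-like cells, the type known for type I interferon secretion, were at 2.17% of control and 1.06% of treated cells, and neutrophil-like cells at 1.42% and 3.10%. Mast cell or basophil-like cells numbered 4 and 12.

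Barcodes outside the immune classes were unevenly spread. Erythroid-like barcodes, which the sort for CD45 and the lysis of red blood cells should remove, made up 12.3% of the control and 1.18% of the treated library, and fibroblast-like cells 3.04% and 1.23%. The fibroblast-like name comes from the marker list only. That cluster was led by Shisal2b, Cald1 and Rhox5 and had little of the Y-linked gene Ddx3y, so its cells may not be host fibroblasts. Unnamed clusters held 18.99% of control and 12.02% of treated cells. Among the named immune cells alone, the monocyte/macrophage-like share was 13.1% in the control and 30.6% in the treated library, the B-like share 5.53% and 10.3%, the T-like share 34.6% and 24.8%, and the NK-like share 32.9% and 22.7%. These shares carry the sort, the minimum of 200 genes per cell and the gap in depth between the libraries. The neutrophil-like difference of 1.69 percentage points turned to -2.23 with at most 10% mitochondrial UMIs and to -2.04 with each library clustered alone, and the NK-like difference of -2.15 points turned to 0.71 with each library clustered alone. In that setting monocyte/macrophage-like cells made up 13.7% and 26.2%, a ratio of 1.91. With at least 500 genes per cell, erythroid-like barcodes made up 10.96% and 6.22%, and plasmacytoid dendritic-like cells 2.15% and 0.590%. The treated erythroid-like count was 348 in that setting and 69 in the main one. A stricter filter adds no cells, so clustering again had changed which barcodes were named erythroid-like.

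**Figure D1:**
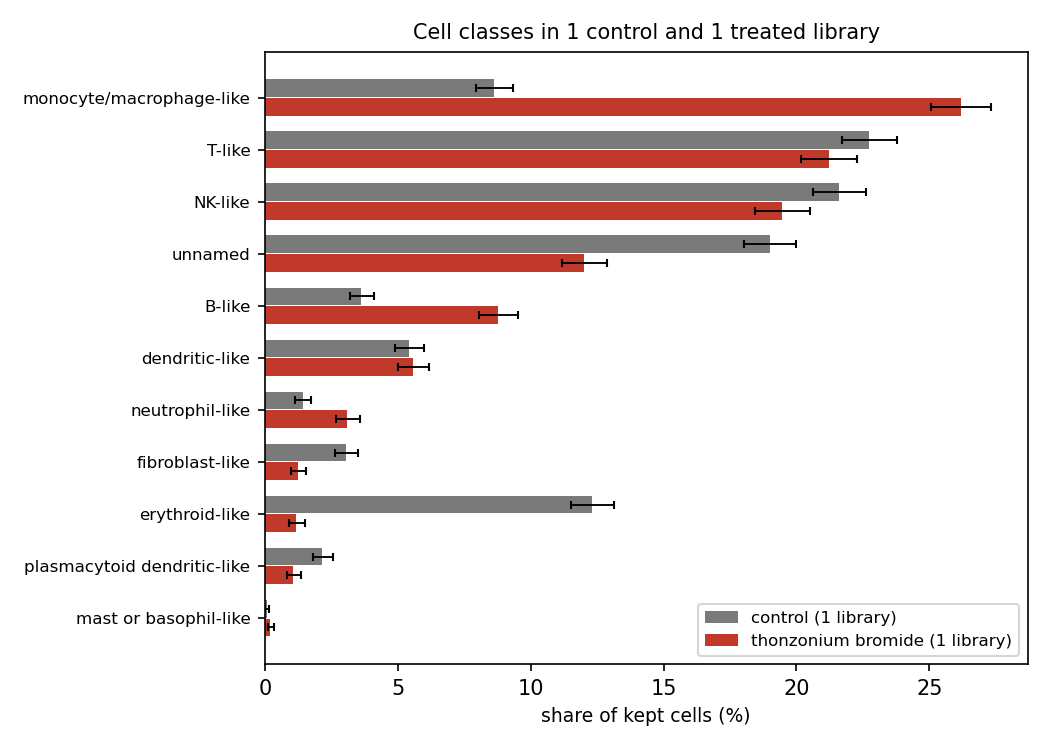
Share of kept cells (%) in each cell class in the control library (grey) and the thonzonium bromide library (red), with exact Clopper-Pearson 95% intervals as error bars. The monocyte/macrophage-like class shows the widest gap, 8.62% against 26.2%.

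Within the T- and NK-like cells, the next question was which lymphocyte types differed. CD8 T-like cells, the cytotoxic T cell lineage, made up 5.27% of the control lymphoid cells (150 of 2846 cells, 4.48 to 6.16) and 14.8% of the treated ones (351 of 2372 cells, 13.4 to 16.3). Regulatory T-like cells, which restrain other T cells and are marked by the transcription factor Foxp3, made up 17.5% (16.2 to 19.0) and 7.63% (6.59 to 8.77). NK-like cells made up 41.0% and 46.4% of these lymphoid cells. By the clusters over all cells, the NK-like class held 1387 of the same 2846 control and 1135 of the same 2372 treated cells. The higher treated share therefore depends on which subclusters were named. An unnamed subcluster whose best list was NK cell held 152 and 44 cells, and 1 of cell cycle genes in which 2 classes tied held 236 and 100. The former was led by H2-Aa, Cd74 and H2-Ab1, with Lyz2 also among its leading genes, at median depths of 1752 and 6893 UMIs. Its NK cell and CD8 T cell lists scored 2.38 and 2.30, so its cells cannot be taken as NK cells. Gamma-delta T-like cells, led by the interleukin 17 gene Il17a, numbered 12 and 43, or 0.422% and 1.81%. Innate lymphoid-like cells numbered 9 and 6. Unnamed subclusters held 35.5% and 29.1%. Among them was a T cell subcluster with Ly6c2, Trdc and Tcrg-C2 among its leading genes, of 496 control and 388 treated cells (17.4% and 16.4%). Its best list was CD8 T cell, with 6 of 6 markers detected, and it stayed unnamed by the block on sister subtypes set after the clusters had been seen. The CD8 T-like shares leave these cells out and depend on that rule. At a clustering resolution of 2 the CD8 T-like share was 12.9% and 20.9%. That setting also named 216 control and 9 treated lymphoid cells erythroid-like (7.59% and 0.379%). They are part of the 2846 and 2372 cells, so the shares above carry them.

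Of the CD8 T-like difference of 9.53 percentage points, 7.97 points lay in a single subcluster, which held 7 control cells (0.246%, 0.0989 to 0.506) and 195 treated cells (8.22%, 7.15 to 9.40). It was led by Gzmk, a granzyme protease of memory-like cytotoxic T cells, Cd8b1, the T cell chemokine gene Ccl5 and Tox, a transcription factor of chronically stimulated T cells. The other CD8 T-like subcluster, led by Cd8a and Gzmf, held 143 and 156 cells (5.02% and 6.58%). A subcluster found mostly in 1 library can belong to that library and not to a cell type. In the treated library the Gzmk-led subcluster had 429 CPM of Pdcd1, the gene of the inhibitory receptor PD-1, against 328 CPM in the other CD8 T-like subcluster. The effector genes Prf1 (340 against 679 CPM) and Gzmb (2184 against 3047 CPM) were lower in the Gzmk-led subcluster, the inhibitory receptor gene Ctla4 was higher (357 against 179 CPM), and those of Lag3 (221 against 247 CPM) and Havcr2 (163 against 187 CPM) had overlapping intervals. The granzyme gene Gzmf was at 3.94 CPM in the Gzmk-led and at 1458 CPM in the other subcluster.

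**Figure D2:**
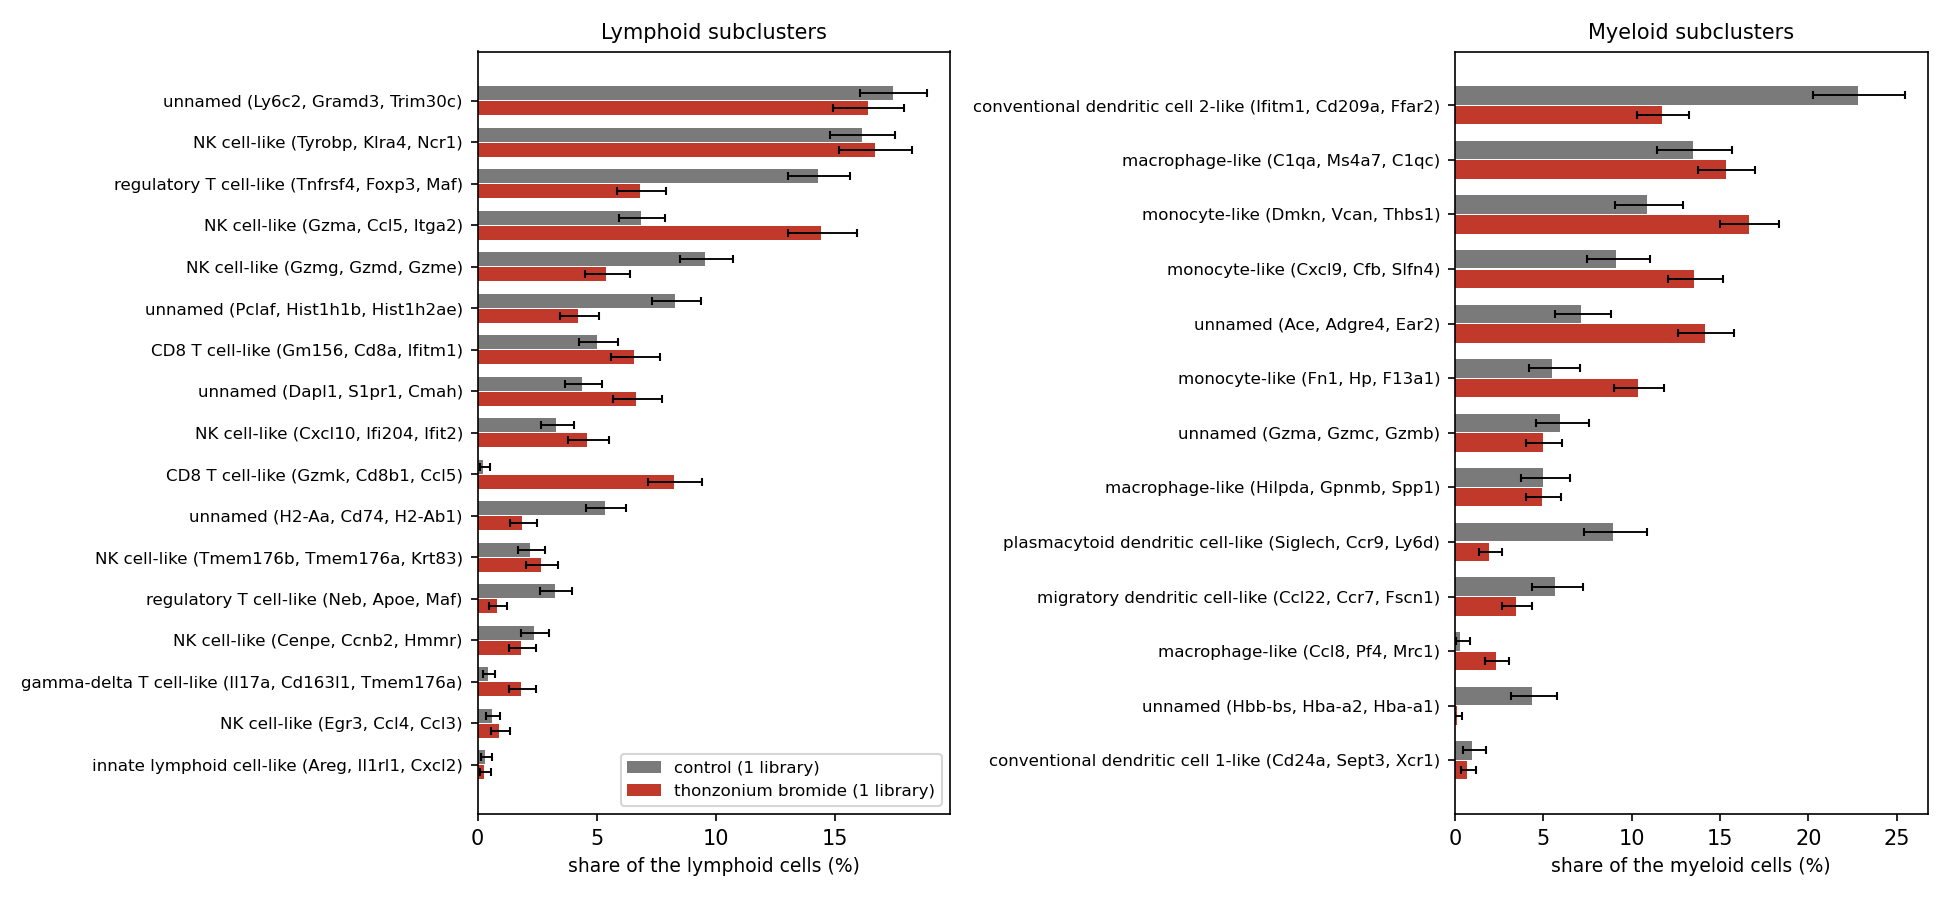
Share (%) of the lymphoid cells (left) and of the myeloid cells (right) in each subcluster, named by type and by 3 leading genes, in the control (grey) and thonzonium bromide (red) libraries, with exact Clopper-Pearson 95% intervals. The Gzmk-led CD8 T-like subcluster holds 0.246% of control and 8.22% of treated lymphoid cells.

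T cell receptor transcripts were examined after the subclusters had been seen. Of its 195 treated cells, 48 had a UMI of a beta chain variable segment, and all 48 carried Trbv13-1 (ENSMUSG00000076467, chromosome 6, 41116007 to 41116468), or 100% (92.6 to 100). Among treated T-like cells outside the subcluster, Trbv13-1 was found in 16 of 220 such cells, or 7.27% (4.21 to 11.5), and among the control ones in 6.51%. The alpha chain segments Trav7d-2 and Trav8d-2 were each found in 21 of the 45 cells with an alpha segment UMI, and both together in 1 cell. The other CD8 T-like subcluster had leading segments as well in the treated library, with Trav5-4 in 26 of 55 cells with an alpha segment UMI (47.3%, 33.7 to 61.2) and Trbv2 in 22 of 56 with a beta one (39.3%, 26.5 to 53.2), against 21.4% (10.3 to 36.8) and 25.6% (13.04 to 42.1) in the control, with intervals that overlap. Variable segments had been left out of the genes used for clustering. No beta chain joining segment was counted in any of these cells, so receptor sequences could not be read.

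**Figure D3:**
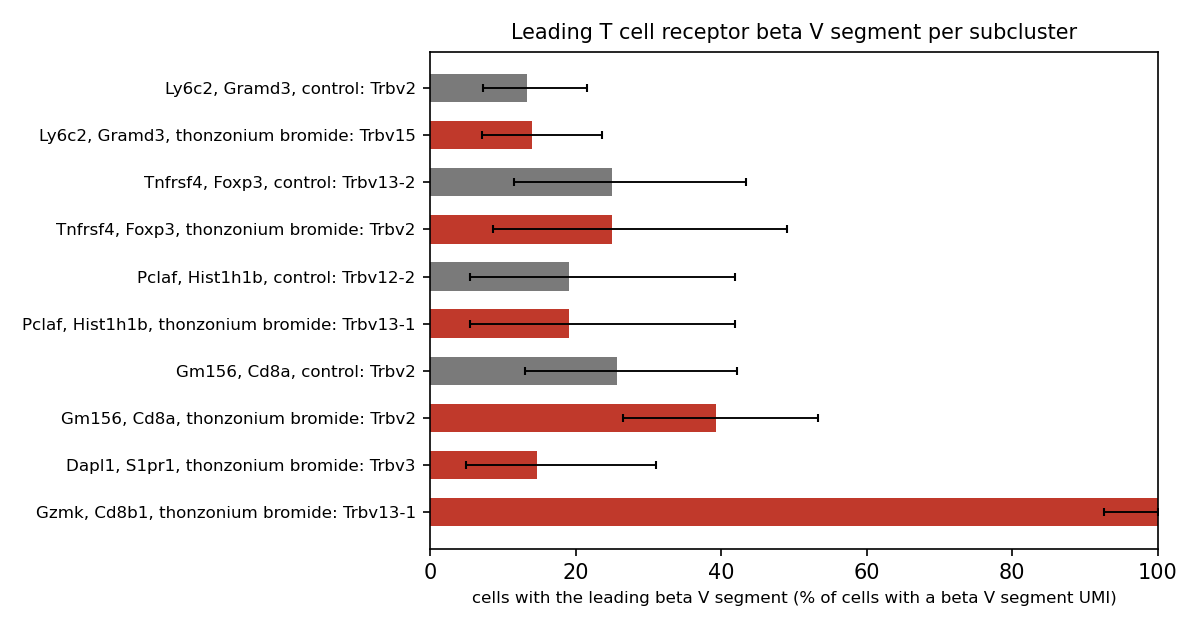
Cells carrying the leading T cell receptor beta variable segment, as % of the cells with any beta variable segment UMI, for each T cell subcluster (named by 2 leading genes) and library with at least 20 such cells, with exact Clopper-Pearson 95% intervals. In the Gzmk-led subcluster of the thonzonium bromide library (red) the share is 100%.

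Over all T-like cells, Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908 in GRCm38) was at 5.80 CPM in the control and 73.2 CPM in the treated library, a ratio of 12.6 (9.65 to 16.8). Ccl5 was 3.19-fold higher (1160 and 3697 CPM), Cxcr6, a homing receptor of tissue-resident T cells, 1.97-fold, Tox 1.97-fold, and Ifng, the gene of the main T cell interferon, 1.88-fold (87.1 and 163.5 CPM). The coreceptor genes Cd8b1 and Cd8a were 1.86-fold and 1.53-fold higher, the orphan nuclear receptor gene Nr4a2 1.94-fold, Themis, a regulator of T cell receptor signalling, 1.76-fold, and the integrin gene Itga4 1.66-fold. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) was at 82.4 CPM (76.8 to 88.2) in the control and 39.4 CPM (35.7 to 43.5) in the treated library. Lower levels were also found for Neb, which encodes a muscle filament protein (117.6 and 45.8 CPM), the heat shock genes Hspa1a and Hspa1b (2.24-fold and 2.27-fold lower), the immediate early gene Jun (1.94-fold lower), and the costimulatory receptor gene Tnfrsf4 (1.81-fold lower).

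Of the gene lists fixed in advance, the regulatory T cell programme was lower in the treated library for 11 of 12 measured members, with a median log2 ratio of -0.60, at percentile 0 of 10000 random lists matched on expression. Its most abundant member, the transcription factor gene Ikzf2, was at 901 and 556 CPM, while Areg, an epidermal growth factor family gene, was at 24.6 and 33.5 CPM, a direction that turned when cells with the highest doublet scores were left out (ratio 0.545). The checkpoint and exhaustion list, which holds inhibitory receptors and their regulators, had a median of 0.21 (percentile 100), with 8 of 14 members higher. Among them Pdcd1 was at 95.4 and 147 CPM and Lag3, another inhibitory receptor gene, at 71.1 and 109 CPM, whereas Ctla4 was at 297 and 198 CPM and Tnfrsf9 at 355 and 228 CPM. The cytotoxic effector list had a median of 0.11 (percentile 99.2, 11 of 17 higher). Lists known from myeloid cells also differed in T-like cells, with medians of -0.33 for complement and resident macrophage (percentile 1.97, but 57.7 after thinning), -0.43 for alternative activation (percentile 0.04, but 0.01 at percentile 64.3 with the same cluster weights) and 0.81 for myeloid chemokine genes (percentile 100, 6 of 10 higher). Ccl3 and Ccl4 of the chemokine list are also in the cytotoxic effector list and among the 10 leading genes of the Gzmk-led subcluster. The chemokine median therefore need not come from myeloid transcripts. Of the chemokine genes in the cytotoxic list, Xcl1 was 1.55-fold lower while Ccl5, its most abundant member, was 3.19-fold higher. Gzmc, a granzyme gene whose UMIs were found in 64.2% of control and 28.7% of treated cells of all classes together, was 2.30-fold lower. Cell cycle genes had a median of -0.18 (percentile 0.50, 17 of 18 lower), with Mki67 and Cenpf 1.58-fold and 1.63-fold lower and Tubb5 at 478 and 482 CPM. Naive and memory genes had a median of -0.15, at percentile 5.04, and Klf2, a regulator of lymphocyte trafficking, was 1.41-fold lower while Dapl1 was at 39.1 and 45.0 CPM.

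Cluster shares within the T-like class differed between the libraries, which the gene levels of the class carry. The regulatory T-like cluster held 36.4% of control and 16.2% of treated T-like cells. Of the CD8 T-like clusters, that led by Cd8a and Cd8b1 held 12.1% and 30.5% and that led by cell cycle genes 8.70% and 5.17%. The cluster led by Trdc and Cd3d held 35.2% and 33.2%, and the cluster of naive genes led by Dapl1 and Lef1 6.85% and 11.3%. With the same cluster weights in both libraries, the medians were 0.07 for the regulatory programme, -0.07 for checkpoint and exhaustion, 0.10 for cell cycle and 0.04 (percentile 78.0) for cytotoxic effector genes, and the ratios of Foxp3 and Tnfrsf4 were 1.03 and 1.04. Without the Gzmk-led subcluster the checkpoint median was 0.03 (percentile 91.8), and the ratios of Gzmk, Ccl5 and Tox were 5.50, 1.71 and 1.08. Ifng and Neb had ratios of 1.21 and 0.734 with the same cluster weights, and the cell cycle median lay at percentile 21.1 with each cell scaled alike and at percentile 9.45 after thinning to 1000 UMIs. The naive and memory median turned to 0.037 after thinning and to 0.016 without the Gzmk-led subcluster, and the thinned cytotoxic effector median was 0.25.

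After thinning each T-like cell to 1000 UMIs, which left out 75 control and 18 treated cells, a Pdcd1 UMI was found in 8.31% of control (6.91 to 9.89) and 11.5% of treated (9.75 to 13.4) T-like cells, with intervals that just overlap, against 0% of thinned B-like cells in both libraries. Lag3 was found in 7.23% and 10.7%, Ifng in 5.06% (3.96 to 6.35) and 10.3% (8.68 to 12.2), Foxp3 in 10.3% (8.78 to 12.1) and 5.50% (4.28 to 6.93), Ctla4 in 20.7% and 14.8%, and the proliferation gene Mki67 in 9.90% and 6.40%. Havcr2, the gene of the inhibitory receptor TIM-3, was found in 6.29% and 6.89%, Tigit in 2.02% and 1.07%, and the perforin gene Prf1 in 10.5% and 12.6%, each with overlapping intervals. Gzmb, a main cytotoxic granzyme gene, was found in 61.3% and 55.6%, with a B-like background of 13.04% and 5.49%, and Prf1 had a B-like background of 5.65% and 1.37%. B-like backgrounds of the other genes lay between 0% and 3.04%. Unthinned, a Pdcd1 UMI was found in 24.6% and 35.7%, a Lag3 UMI in 23.7% and 35.0%, an Ifng UMI in 19.4% and 30.0%, a Foxp3 UMI in 20.4% and 10.8%, a Ctla4 UMI in 36.1% and 33.2%, a Mki67 UMI in 21.9% and 17.9%, a Havcr2 UMI in 19.3% and 25.1%, a Tigit UMI in 7.68% and 6.39%, a Prf1 UMI in 32.2% and 42.1%, and a Gzmb UMI in 82.5% and 76.3%. Unthinned B-like backgrounds were 12.9% and 5.86% for Prf1 and 33.9% and 11.9% for Gzmb, and between 0% and 4.29% for the other genes. Median depths were 5233 and 6792 UMIs in T-like cells and 3861 and 3720 in B-like cells.

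In NK-like cells, the cytotoxic effector list was higher in the treated library for 13 of 16 members, with a median log2 ratio of 0.13 at percentile 99.95. Transcripts of other cell types also differed in this class, with medians of -0.45 for complement and resident macrophage genes (percentile 0.15, 9 of 10 lower) and 0.58 for neutrophil granule genes (3 of 4 higher, but percentile 91.2 with each cell scaled alike). Ccl5 was 2.43-fold higher (939.5 and 2286 CPM) and Gzma, an abundant granzyme gene of mature NK cells, 1.54-fold (3262 and 5016 CPM). The integrin genes Itga2, Itgb2 and Itgax were 1.52-fold, 1.46-fold and 1.39-fold higher, Cd7 1.86-fold, and the Ly49 receptor genes Klra9 and Klra4 1.40-fold and 1.37-fold. Lower levels were found for Gzmg, another granzyme gene (126 and 46.3 CPM, 2.73-fold lower), the immediate early genes Jun and Fosb (1.96-fold and 1.83-fold lower), and the proliferation genes Mki67 and Cenpe (1.81-fold and 1.51-fold lower). Gzmc, the most abundant member of the cytotoxic list, was at 8957 and 7257 CPM. The Gzma-led NK-like cluster held 33.6% of control and 51.3% of treated NK-like cells, the Gzmc-led cluster 46.3% and 41.8%, and the cluster of cell cycle genes 20.1% and 7.0%, at median depths of 2073 and 17097 UMIs in the last. The Gzmg ratio moved from 0.367 to 0.621 after thinning to 1000 UMIs, and the Mki67 ratio from 0.554 to 0.363 with each cell scaled alike.

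The monocyte/macrophage-like cells were compared for activation and metabolic genes, since thonzonium bromide targets proton pumps of endosomes and lysosomes. Interferon-gamma-inducible genes were higher in the treated library for 16 of 18 members, with a median log2 ratio of 0.32 (percentile 100), and MHC class II presentation genes, which display antigen to CD4 T cells, for 11 of 12, with a median of 0.42 (percentile 100). Complement and resident macrophage genes were lower for 10 of 12 members (median -0.41, percentile 0), and hypoxia genes for 14 of 14 (median -0.48, percentile 0). V-ATPase subunit genes, which encode the proton pump, had a median of 0.00 at percentile 25.1, with Atp6v0d1 1.24-fold higher and Atp6v1h at 66.4 and 62.0 CPM. Lysosome genes had a median of 0.06 at percentile 76.5, with the enzyme activator gene Psap 1.16-fold higher and the membrane protein gene Cd63 1.42-fold lower.

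Among the interferon-gamma-inducible genes, Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), a chemokine that draws activated T cells, was at 82.2 CPM (74.0 to 91.0) in the control and 307 CPM (299 to 316) in the treated library, a ratio of 3.74 (3.36 to 4.17). The guanylate-binding protein gene Gbp2 was 1.88-fold higher, the immunity-related GTPase gene Iigp1 1.68-fold and the serpin gene Serpina3g 2.12-fold, while Cxcl10 was at 2659 and 2457 CPM and Socs1, a feedback inhibitor of cytokine signalling, at 104 and 89.1 CPM. MHC class I presentation genes had a median of 0.16 (percentile 99.5, 14 of 15 higher), with Tapbp and Tap2, which load peptides, each 1.22-fold higher and H2-K1 1.06-fold lower. Type I interferon-stimulated genes had a median of -0.12 (percentile 0.08, 14 of 19 lower), with Isg15, a ubiquitin-like antiviral gene, 1.16-fold and Bst2 1.23-fold lower. Further genes above the control were Ccl8, a monocyte-attracting chemokine gene (4.46 and 60.1 CPM), the acute phase gene Saa3 (4.27-fold) and Chil3, a chitinase-like gene of monocytes (2.11-fold). Ccl8, Saa3 and the selenoprotein gene Selenop are among the leading genes of a macrophage-like subcluster of 3 control and 44 treated cells. Lists known from other cell types moved as well in this class, with medians of -0.91 for cytotoxic effector, -0.82 for regulatory T cell and 0.64 for neutrophil granule genes. S100a8 of the neutrophil list was among the leading genes of the monocyte-like subclusters led by Dmkn and by Fn1, the latter also with Lcn2 and Mmp8. These subclusters held 10.9% and 5.48% of control and 16.6% and 10.3% of treated myeloid cells. The neutrophil list median therefore need not come from other cell types.

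Of the resident macrophage genes, Apoe, which encodes a lipid carrier, was at 1583 and 1111 CPM and Ms4a7, a membrane protein gene of macrophages, at 447 and 272 CPM, whereas Selenop was 1.47-fold higher. Among hypoxia genes, the angiogenic factor Vegfa was at 102 CPM (92.9 to 112) and 53.5 CPM (49.9 to 57.3), Ankrd37 1.63-fold lower and the cytokine gene Mif, the most abundant member, 1.26-fold lower. Glycolysis genes had a median of -0.10 (percentile 1.07, 12 of 15 lower), with the enzyme gene Tpi1 1.23-fold lower and Pkm 1.09-fold higher. Cholesterol synthesis genes had a median of 0.17 (percentile 99.6, 14 of 17 higher), with Fdps, an enzyme gene of isoprenoid synthesis, 1.54-fold higher. Inflammatory cytokines (median -0.06, percentile 11.6) and alternative activation genes (median -0.09, percentile 6.82) lay within the central 95% of random lists. Of these, the interleukin gene Il6 was at 14.0 and 6.35 CPM and Nos2, the inducible nitric oxide synthase gene, at 12.2 and 22.2 CPM. The platelet factor gene Pf4 and the chemokine gene Ccl7 were 2.11-fold and 1.67-fold lower, and the heat shock gene Hspa1b and immediate early gene Fosb 1.73-fold and 1.86-fold lower. After thinning to 1000 UMIs, MHC class I presentation (median 0.10, percentile 80.5) and cholesterol synthesis (0.16, percentile 81.2) fell within the central 95%, and alternative activation left it (-0.25, percentile 0.55). The inflammatory median turned to 0.17 after thinning, to 0.10 with each cell scaled alike and to 0.043 with at least 200 UMIs per gene. The glycolysis median was -0.06 (percentile 4.31) with the same cluster weights, and thinned ratios were 1.95 for Saa3, 8.84 for Ccl8, 3.90 for Nos2 and 0.217 for Il6.

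Of the monocyte/macrophage-like class, the cluster led by the complement genes C1qb and C1qa held 50.3% of control and 43.6% of treated cells. That led by Vcan and Chil3 held 31.3% and 33.9%, and that led by Lyz2 and Hp 18.4% and 22.5%. Gene levels of the class carry the lower treated share of the complement-led cluster. Of the myeloid cells clustered alone, monocyte-like cells made up 25.5% (265 of 1040) and 40.5% (775 of 1914) and macrophage-like cells 18.8% and 22.5%. Type 2 conventional dendritic-like cells made up 22.8% and 11.7% (237 and 224 cells), migratory dendritic-like cells 5.67% and 3.45% (59 and 66), and plasmacytoid dendritic-like cells 8.94% and 1.93% (93 and 37). The larger treated myeloid total lowers these shares. Of all kept cells, the type 2 cluster held 4.36% and 4.73% and the migratory cluster 1.06% and 0.840%, each with overlapping intervals. Type 1 conventional dendritic-like cells numbered 10 and 13. Chil3, a monocyte marker, and Cxcl9 and Gbp2, which lead monocyte-like clusters, themselves differed between the libraries. The macrophage-like difference of 3.77 points was -0.09 points with at least 500 genes per cell. An unnamed subcluster led by Ace, Adgre4 and Treml4 held 7.12% and 14.2%, and another led by the lymphocyte genes Gzma and Trbc2, with the highest doublet scores, 5.96% and 4.96%.

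In thinned monocyte/macrophage-like cells, a Cxcl9 UMI was found in 4.54% of control (2.96 to 6.63) and 10.2% of treated cells (8.71 to 11.8), against 0.289% and 0.328% of T-like cells, and a UMI of the MHC class II gene H2-Ab1 in 24.1% and 30.0%, against 4.48% and 2.95% of T-like cells. Shares were 14.5% and 14.3% for Cd274, the gene of PD-L1, with a T-like background of 7.08% and 6.40%. They were 4.17% and 4.27% for the arginase gene Arg1, 2.36% and 3.09% for the mannose receptor gene Mrc1, and 0.726% and 1.77% for Nos2, with backgrounds between 0% and 0.145%. Intervals overlapped for H2-Ab1, Cd274, Arg1, Mrc1 and Nos2. Unthinned shares were 9.58% and 18.6% for Cxcl9, 44.8% and 52.4% for H2-Ab1, 50.3% and 54.1% for Cd274, 11.6% and 9.56% for Arg1, 8.86% and 10.3% for Mrc1, and 3.62% and 4.72% for Nos2, with T-like backgrounds of 28.7% and 30.6% for Cd274, 17.2% and 17.0% for H2-Ab1 and between 0.137% and 1.54% for the others. Thinning left out 2 control and 5 treated cells, at median depths of 7493 and 9744 UMIs.

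**Figure D4:**
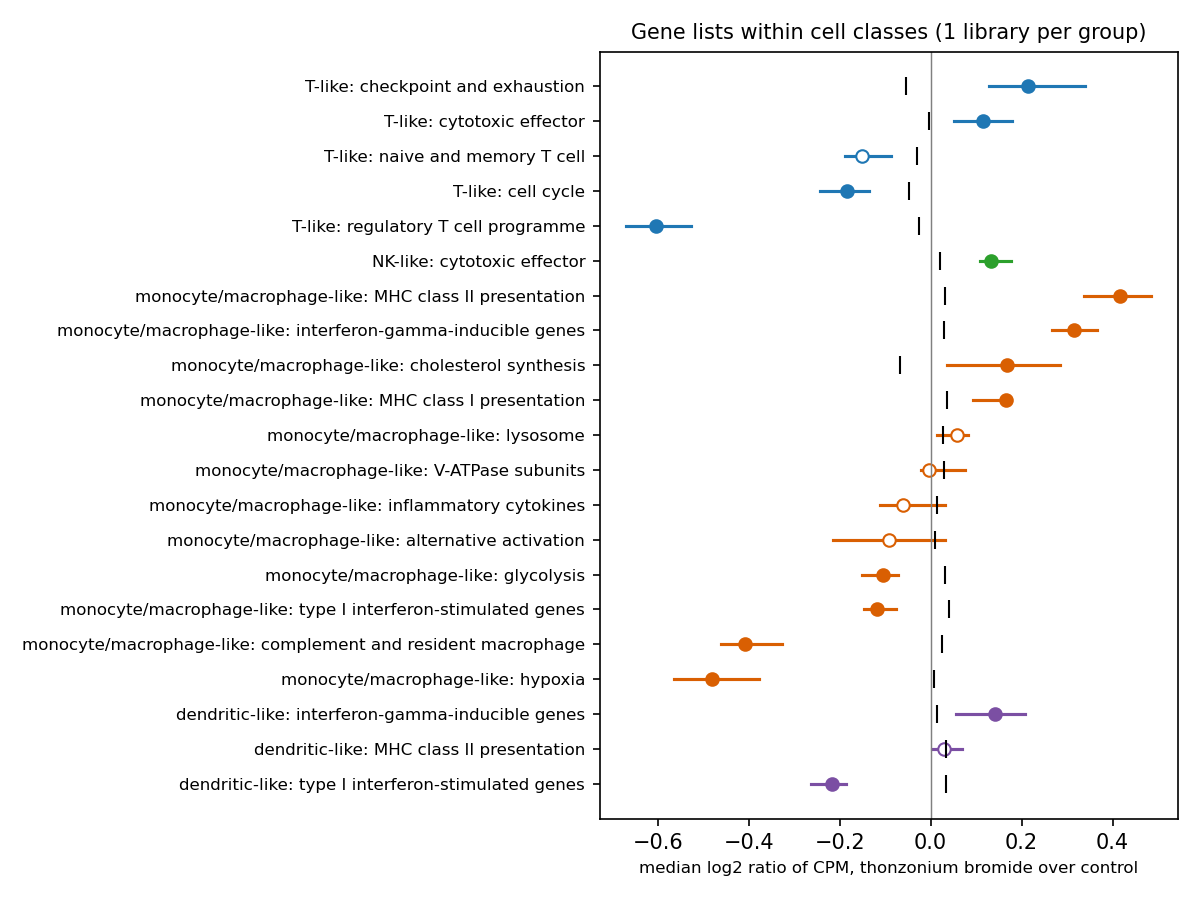
Median log2 ratio of CPM, thonzonium bromide over control, over the measured members of the gene lists on the axis within T-like (blue), NK-like (green), monocyte/macrophage-like (orange) and dendritic-like (purple) cells. Lines are 95% counting intervals from Poisson redraws, black ticks the median of matched random lists, and filled points lie outside the central 95% of those lists.

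Dendritic-like cells differed in both interferon lists, in opposite directions. Type I interferon-stimulated genes were lower in the treated library for 18 of 19 members (median -0.22, percentile 0.02), with Isg15 1.32-fold and Bst2 1.41-fold lower. Interferon-gamma-inducible genes were higher for 13 of 17 (median 0.14, percentile 99.3), with Cxcl9 2.10-fold and Gbp2 1.73-fold higher and Cxcl10 1.21-fold lower. MHC class II presentation genes had a median of 0.03 (percentile 44.9), with the class II chaperone gene Cd74 1.15-fold higher and the costimulatory ligand gene Cd80 1.61-fold lower. The cluster of type 2 conventional dendritic-like cells held 80.5% of control and 84.9% of treated dendritic-like cells. With each cell scaled alike, the interferon-gamma-inducible median lay at percentile 96.9 and the MHC class II median was 0.16, and after thinning to 1000 UMIs these medians were 0.29 and 0.17. Transcripts of other cell types also differed in this class, with medians of -0.27 for cytotoxic effector (percentile 0.06), -0.29 for regulatory T cell (percentile 2.58, within the central 95%) and 0.25 for complement and resident macrophage genes (percentile 99.9, but 79.9 with each cell scaled alike).

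Among the highest ratios in B-like cells, Cd22, an inhibitory coreceptor gene of B cells, was 1.74-fold higher (130 and 226 CPM), the MHC class II genes H2-Oa and H2-Eb2 1.65-fold and 1.67-fold, and Hhex, a transcription factor gene, 1.59-fold. The heat shock genes Hsph1, Dnajb1 and Hspa1a were 2.99-fold, 2.91-fold and 2.75-fold lower, and the activation marker gene Cd69 2.37-fold lower (993 and 419 CPM). Klf4, a transcription factor gene of resting lymphocytes, was 2.23-fold, Cxcr4, a chemokine receptor gene, 2.12-fold and the NF-kappaB gene Rel 2.10-fold lower. Some transcripts of other cell types were also higher in the treated B-like cells. The cytotoxic effector median was 0.50 (percentile 100, 10 of 14 higher) and the neutrophil granule median 1.69 (2 of 3 higher). Gzma was at 235 and 495 CPM, the macrophage gene Lyz2 at 22.2 and 121 CPM and the muscle gene Acta1 at 0 and 94.0 CPM. Gzmc was lower, at 627 and 472 CPM. Fewer treated B-like cells had a UMI of Gzmc (48.9% and 13.7%) or, unthinned, of Gzmb (33.9% and 11.9%). The higher cytotoxic median was therefore no rise across all B-like cells. Scaling by the median of gene ratios moved the median log2 ratio of all B-like genes from -0.08 to 0.05, so ratios near 1 in this class depend on scaling.

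Neutrophil-like cells numbered 91 in the control and 181 in the treated library, too few for gene list medians under the minimum of 200 cells. After thinning, a Cd274 UMI was found in 57.5% (46.4 to 68.0) and 45.8% (38.3 to 53.4) of them, and a UMI of the interleukin gene Il1b in 94.3% and 97.7%, with overlapping intervals. T-like backgrounds were 7.08% and 6.40% for Cd274 and 1.95% and 2.21% for Il1b. Unthinned, the shares were 72.5% and 63.0% for Cd274 and 97.8% and 98.9% for Il1b, against 28.7% and 30.6% and 6.79% and 10.99% of T-like cells, at median depths of 3341 and 3507 UMIs.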

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

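The tests below were chosen after the results had been seen, except the number of libraries per group, the thinned Foxp3 share and the joining segment test, which were written down before. T cell receptor variable segments, left out of the main comparisons, showed a signal above the control library: Trbv13-1 was found in 23.88% (18.9 to 29.4) of the treated T-like cells with a beta variable segment UMI, against 6.48% (3.59 to 10.6) in the control.

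The Gzmk-led CD8 T-like subcluster held 7 control and 195 treated cells. A library shift that sorts the same cells into different subclusters did not account for it, since over all T-like cells, whatever their subcluster, the Trbv13-1 share differed by 17.4 points, against 6.51% and 7.27% outside the subcluster, and neither did doublets, since its median depth was 0.901 times that of the other treated T-like cells. The pattern fits a single expanded T cell clone by the beta chain, with Trbv13-1 in 100% (92.6 to 100) of the cells with a beta variable segment UMI, while Trav7d-2 and Trav8d-2, each in 21 cells, met in 1 cell against 2.26 if independent, too few to decide. Joining segments, the test written before, could not tell, since 0 cells had a beta joining segment UMI and only 2 an alpha one, of different segments. A shared beta segment may come from 1 clone or from several clones with the same segment, and a clone in 1 tumour can arise with or without the drug, so a treatment effect could not be told apart.

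Monocyte/macrophage-like cells had a 3.04-fold higher share in the treated library. An excess of erythroid-like, non-immune and unnamed barcodes in the control did not account for it, since among named immune cells the ratio was 2.33 (2.11 to 2.57). Low-depth monocytes or macrophages among the unnamed barcodes of the control cannot be told apart as an explanation. Counting all of the control's unnamed cells as such, and none of the 701 unnamed treated cells, gave 27.6% against 26.2%, a ratio of 0.948. This is an extreme setting that moves cells of the control only, although the largest unnamed clusters held cells of both libraries. Classes from marker scores per cell, with none unnamed, gave 10.9% and 25.7%. A difference between tumours or sorts without any drug effect could not be told apart from the treatment with 1 library per group.

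The regulatory T-like cluster held 36.4% of the control and 16.2% of the treated T-like cells. Dilution by the Gzmk-led subcluster did not account for this, since without it the shares were 36.6% and 19.3%, a difference of -17.3 points. Depth did not either, since after thinning a Foxp3 UMI was found in 10.3% and 5.50% of T-like cells, a difference of -4.84 points. Low-depth barcodes did not, since with at least 500 genes the shares were 35.0% and 15.8%, a difference of -19.2 points. Whether the drug or the tumour sampled gave this difference was not tested, because no group has a second library.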

How the results depend on the processing

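Settings named below as added were chosen after the results had been seen. Leaving out a replicate is not possible with 1 library per group. No paired analysis was possible because the labels pair no samples. Removing Scrublet doublets was not run apart from the main setting, since Scrublet marked 1 cell. The cause of a shift was not tested unless stated. A change of sign is called reversed only where, in the main setting, a list median lay outside the central 95% of random lists, or the counting interval excluded 0 for a difference or 1 for a gene ratio. The dendritic-like share (0.150 points in the main setting), the naive and memory median in T-like cells and the inflammatory median in monocyte/macrophage-like cells changed sign below without meeting this. The dendritic-like difference was also -0.129 with at most 10% mitochondrial UMIs, -0.0284 without the highest doublet scores, -0.192 at resolution 2 and -0.523 from marker scores per cell. Of 71 class share values under alternatives, 48 stayed within the counting interval, 20 moved and 3 reversed. Of 33 subclass values the counts were 28, 4 and 1, of 194 list medians 155, 36 and 3, of 54 UMI shares 38, 16 and 0, and of 1709 gene ratios 1432, 259 and 18. The class share counts leave out unnamed and mast cell or basophil-like cells, which also changed sign. The unnamed difference went from -6.97 points to 1.35 with each library clustered alone. The mast cell or basophil-like difference went from 0.143 to -0.391 from marker scores per cell. The monocyte/macrophage-like and B-like shares and the regulatory T-like and CD8 T-like shares kept their direction in these settings. With all of the control's unnamed cells, and none of the treated library's, counted as monocyte/macrophage-like, the ratio of that share was 0.948. Depth limits the shares of cells with a UMI, whose unthinned gaps carry the deeper treated library.

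Differences in share (treated minus control, percentage points) were, with at least 500 genes, -4.79 for NK-like, -4.98 for T-like, -0.674 for dendritic-like, -4.74 for erythroid-like and -1.56 for plasmacytoid dendritic-like cells, and -0.0867 for macrophage-like (reversed) and -9.86 for plasmacytoid dendritic-like cells of the myeloid cells. With at most 10% mitochondrial UMIs they were -4.13 for T-like, -9.44 for erythroid-like and -2.23 for neutrophil-like cells (reversed). With each library clustered alone they were 0.713 for NK-like (reversed), -0.750 for dendritic-like, 12.5 for monocyte/macrophage-like and -2.04 for neutrophil-like cells (reversed). At resolution 2 they were -6.29 for erythroid-like and 13.2 for monocyte/macrophage-like cells. From marker scores per cell they were -0.0153 for NK-like, -3.40 for T-like, 14.8 for monocyte/macrophage-like, 0.954 for neutrophil-like and -1.99 for plasmacytoid dendritic-like cells. Among named immune cells (added), where leaving out erythroid-like and unnamed barcodes raises the control shares by construction, they were -10.2 for NK-like, -9.84 for T-like, -1.75 for dendritic-like and -2.06 for plasmacytoid dendritic-like cells. Subclustered at resolution 0.5, they were 7.95 for macrophage-like, 10.3 for monocyte-like and -10.5 for plasmacytoid dendritic-like cells.

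Median log2 ratios under the same cluster weights, which by construction remove differences in cluster shares, were, in T-like cells, 0.041 for cytotoxic effector, -0.067 for checkpoint and exhaustion, 0.066 for regulatory and 0.10 for cell cycle genes, the last 3 reversed. In monocyte/macrophage-like cells they were 0.18 for MHC class I, -0.31 for complement, 0.10 for lysosome, -0.063 for glycolysis and -0.35 for hypoxia genes. Reversed gene ratios in that setting were 1.03 for Foxp3, 1.04 for Tnfrsf4, 0.990 for Dapl1, 1.05 for Il7r, 1.75 for Il10 and 0.935 for Havcr2 in T-like cells, and 1.00 for H2-K1 in monocyte/macrophage-like cells. Without the Gzmk-led subcluster (added), T-like medians were 0.028 for checkpoint, 0.016 for naive and memory, -0.51 for regulatory and -0.032 for cell cycle genes, and Il7r (1.02) and Havcr2 (0.961) reversed.

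After thinning to 1000 UMIs, T-like medians were 0.25 for cytotoxic, 0.037 for naive and memory and -0.71 for regulatory genes, and the NK-like cytotoxic median 0.19. Monocyte/macrophage-like medians were 0.26 for interferon-gamma-inducible, 0.17 for inflammatory, -0.25 for alternative activation, -0.17 for glycolysis and -0.67 for hypoxia genes, and dendritic-like medians 0.17 for MHC class II and 0.29 for interferon-gamma-inducible genes. Reversed ratios were 1.05 for Hist1h1d, 0.989 for Atp6v0c, 1.00 for Higd1a and 1.37 for Arg1 in monocyte/macrophage-like cells, and 0.993 for Ciita and 1.44 for Socs1 in dendritic-like cells.

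With each cell scaled alike, medians were 0.21 for cytotoxic, -0.026 for naive and memory and -0.76 for regulatory genes in T-like cells, 0.22 for cytotoxic genes in NK-like cells, -0.16 for type I interferon and 0.10 for inflammatory genes in monocyte/macrophage-like cells, and 0.16 for MHC class II and -0.16 for type I interferon genes in dendritic-like cells. Areg in T-like (0.898) and Arg1 in monocyte/macrophage-like cells (1.19) reversed. Scaled by the median of gene ratios, T-like medians were 0.18 for cytotoxic, -0.084 for naive and memory and -0.12 for cell cycle genes. With at least 200 UMIs per gene, monocyte/macrophage-like medians were 0.23 for interferon-gamma-inducible and 0.043 for inflammatory genes, from fewer members. Without the 5% of cells with the highest doublet scores (added), medians were -0.67 for regulatory genes in T-like and -0.46 for complement genes in monocyte/macrophage-like cells, and Areg in T-like cells reversed (0.545).

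Differences in the share of T-like cells with a UMI, thinned to 2000 UMIs, were 6.91 points for Pdcd1, 6.12 for Lag3, -7.87 for Foxp3, 7.46 for Ifng and -5.97 for Mki67, and 2.25 for Mrc1 in monocyte/macrophage-like cells. Unthinned they were 11.04 for Pdcd1, -2.90 for Ctla4, 11.3 for Lag3, 5.80 for Havcr2, -9.67 for Foxp3, 10.6 for Ifng and 9.90 for Prf1, and 3.82 for Cd274 and 9.01 for Cxcl9 in monocyte/macrophage-like cells. Thinned to 500 UMIs, the Ifng difference was 2.33.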

Other observations

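The gene lists below were computed for every class as planned, but which of them to describe was chosen after the results had been seen. Type I interferon-stimulated genes, known for antiviral defence, were lower in the treated library in lymphocytes as well. In B-like cells 18 of 19 members were lower, with a median log2 ratio of -0.66 (percentile 0), among them Ifit2 (223 and 114 CPM), Ifit1 (188 and 98.8 CPM) and Bst2 (360 and 229 CPM). In T-like cells 19 of 19 members were lower (median -0.17, percentile 0.43), with Isg15 at 794 and 613 CPM, and in NK-like cells 18 of 19 (median -0.17, percentile 0), with Isg15 at 359 and 284 CPM. With each cell scaled alike, the T-like type I interferon median lay at percentile 4.58. Immediate early and dissociation genes, known to respond to tissue handling, were lower for 13 of 13 members in B-like cells (median -0.68, percentile 0.01), with Fos at 514 and 264 CPM, and for 13 of 15 members in T-like cells (median -0.34, percentile 0.01), with Jun at 751 and 387 CPM. Their medians were -0.16 (percentile 0.13) in NK-like, -0.17 (percentile 0.23) in dendritic-like and 0.04 (percentile 52.5) in monocyte/macrophage-like cells. MHC class II presentation genes were higher for 9 of 11 members in B-like cells (median 0.29), with H2-Eb1 at 2156 and 2932 CPM.

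Cholesterol synthesis genes, which encode enzymes of the mevalonate pathway, were lower in the treated library in T-like, NK-like and dendritic-like cells. In T-like cells 15 of 20 members were lower (median -0.39, percentile 0.03), with Hmgcs1 at 26.0 and 19.5 CPM and Idi1 at 19.0 and 11.5 CPM. In NK-like cells 18 of 20 were lower (median -0.30), with Hmgcs1 at 32.6 and 22.9 CPM, and in dendritic-like cells 15 of 16 (median -0.38), with Hmgcs1 at 89.1 and 59.0 CPM. After thinning to 1000 UMIs, the dendritic-like median lay at percentile 11.8. Cell cycle genes were lower for 18 of 18 members in NK-like cells (median -0.51, and -0.22 with the same cluster weights), with Top2a at 67.3 and 42.7 CPM and Stmn1 at 137 and 102 CPM. Hypoxia genes were lower for 11 of 12 members in NK-like (median -0.22) and for 11 of 12 in dendritic-like cells (median -0.29), with Vegfa at 52.0 and 38.5 CPM in NK-like cells. Neutrophil granule genes were higher for 8 of 8 members in monocyte/macrophage-like cells (median 0.64), with S100a8 at 109 and 463 CPM and S100a9 at 34.3 and 91.0 CPM. The few measured members of the same list had medians of 1.69 in B-like (2 of 3 higher), 0.71 in T-like (2 of 3), 0.58 in NK-like (3 of 4) and 0.50 in dendritic-like cells (3 of 4), and a UMI of the neutrophil gene S100a9 was found in 4.52% of control and 12.2% of treated T-like cells.

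The fibroblast-like cluster had Rhox5, a homeobox gene, at 608 and 570 CPM, Cald1 at 669 and 568 CPM and Col3a1 at 321 and 271 CPM. It had Ptprc, the gene of CD45, at 36.1 and 156 CPM, and the Y-linked gene Ddx3y at 1.74 and 4.77 CPM, against 54.6 to 181 CPM in the immune classes. Ddx3y was also low in erythroid-like barcodes, at 15.4 and 3.79 CPM. The fibroblast list had 5 of 7 markers detected in this cluster. Of the epithelial or carcinoma markers, Krt8 had 1 and 2 UMIs in it and Epcam 0 and 0. Whether its cells were host fibroblasts or MFC tumour cells was not tested, and no other explanation for these values was tested.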
